A study of Mus musculus with 4 samples.

How the data were processed

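Single-cell RNA sequencing of 4 mouse cell populations was analysed, 1 library for each of the groups ES-NMP, Epi-CE, Epi-CE-T and Epi-NMP, which were assigned from the sample titles. Per the labels' protocols, 8700 cells of each population were loaded into the 10x Chromium system, and libraries were sequenced on a HiSeq 4000. Per the submitters' processing notes, Cell Ranger 1.3.1 and Seurat 2.0 were used with genome build mm10. Alignment settings, the gene annotation, the treatment of reads that map to several places and the use of strand were not given in the sources used here. The deposited matrix holds whole-number UMI counts per gene and cell, as the authors made them and before any normalization. Each barcode's library came from a deposited cell table. A further column of that table marks each barcode TRUE or FALSE, and what the mark means was not given in the sources used here. On the file itself every TRUE barcode had more than 8000 UMIs and more than 2500 detected genes, and 80 of the 1857 FALSE barcodes passed both minimums as well. All 10579 barcodes were used in the main results. Of 27998 genes, 20460 had at least 1 count and 7538 had none. No GFP reporter sequence was analysed here.

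Counts were summed over all cells of a library and divided by the library's total of gene counts, in units of 1000000 (CPM). Library totals ran from 29927826 in Epi-NMP to 72982631 in ES-NMP, so a floor of 3 counts corresponds to 0.100 CPM in Epi-NMP and 0.0411 CPM in ES-NMP. Ratios of CPM carry exact conditional-binomial 95% intervals, single levels exact Poisson intervals and shares of cells exact Clopper-Pearson intervals. These cover counting error only, and with 1 library per group no test across samples was run and no p-value was computed. A gene with 0 counts in one library was set to the floor, and its ratio is given as a bound. The comparisons were Epi-CE over ES-NMP, Epi-NMP over ES-NMP, Epi-NMP over Epi-CE, and Epi-CE-T over Epi-CE.

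The comparisons, 31 gene lists (377 genes, of which 1, Rian, was not in the table), the markers of 15 cell classes, the named-gene rule and the alternatives to be tried were fixed before the data were examined. Of each list, the members with at least 50 UMIs over both libraries were measured. Its median log2 ratio has an interval from 1000 Poisson resamples of the counts and a percentile among 10000 random lists of the same size, drawn from the same 20 bins of mean expression. Members at least 1.5-fold higher or lower were counted. The named genes of a comparison were the 10 with the highest and the 10 with the lowest ratio among genes with at least 200 UMIs over both libraries and 50 CPM in the higher one. Ribosomal protein, mitochondrial and predicted genes were left out, which kept 2924 to 2997 genes to rank. To these were added 2 to 4 list members with the largest ratios, and T, Sox2, Nkx1-2 and Cdx2 in every library. Some of the genes picked in these ways are not reported here. Gene coordinates came from GENCODE release M21 on GRCm38, the assembly also called mm10.

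For shares of cells with T and Sox2, each cell was thinned at random without replacement to 4000 UMIs, the 10th percentile of the shallowest library rounded down to a step of 500, and shallower cells were left out. For clustering, counts were normalised to 10000 per cell and log-transformed, 2000 variable genes were scaled with a maximum of 10, and 30 principal components, 15 neighbours and Leiden resolution 1.0 were used. A cluster took a class name when at least 3 markers of that class had 5 CPM or more and were at least 2-fold above the other cells. The name also needed more markers of that class than of any other. At least 1 marker had to be among the 10 genes with the highest fold (20 CPM or more, pseudocount 1), and no other class could have more there. Only the fibroblast name was also checked for genes that go against it, namely epithelial genes. The markers were fixed in advance, but parts of this naming rule were tightened after the first clustering had been seen. Scrublet marked 45 of the 10579 cells (0.425%) as doublets, which is too few for a caller that worked on so many cells. All cells were kept, and removing the 5% of cells with the highest Scrublet score in each library was added as an alternative after the data had been seen. The same holds for using TRUE barcodes alone, for leaving out the naive pluripotent-like cells, and for the other scalings of the lists besides the NMP list.

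Cells with and without a T UMI were compared within each library from thinned counts, and the resulting ratios were correlated across genes with Epi-CE-T over Epi-CE ratios from cells that shared none with them. Alternatives fixed in advance were scaling by TMM factors or DESeq2 size factors, library totals without ribosomal and mitochondrial genes, no minimum on list members, the mean of per-cell CPM, cells between the 10th and 90th percentile of UMIs, removal of Scrublet calls, unthinned counts, thinning to 2000 UMIs, at least 2 UMIs, another random seed, Leiden resolutions 0.5 and 2.0, variable genes without cell cycle genes, and clustering of each library by itself. TMM and DESeq2 scaling shifted the log2 ratios of all genes by at most 0.06.

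The ratio step was tested on simulated Poisson counts drawn from the real means and totals with changed genes. No variation between cells or libraries was simulated, so coverage near 95% follows from the design and checks only the calculation. For Epi-CE over ES-NMP, run on 11222 genes, 98.5% of intervals of genes changed 1.5-fold excluded 1 in the true direction, and 95.3% of the intervals of unchanged genes held 1. For Epi-NMP over ES-NMP (10752 genes) these shares were 98.5% and 95.4%, for Epi-NMP over Epi-CE (10634 genes) 98.5% and 95.1%, and for Epi-CE-T over Epi-CE (10907 genes) 100% and 95.2%. Genes changed 2-fold or 4-fold were recovered in 100% of cases in each comparison. For cells with and without T, 1.5-fold changes were recovered in 98.5% of cases in ES-NMP (5748 genes), 79.0% in Epi-CE (5019 genes), 86.2% in Epi-CE-T (4840 genes) and 98.5% in Epi-NMP (4881 genes). Intervals of unchanged genes excluded 1 in 4.91%, 5.13%, 4.84% and 8.40% of cases in the same order, and intervals of genes changed 1.5-fold held the true value in 95.5%, 91.9%, 94.8% and 87.9%, so in Epi-NMP small differences between cells with and without T are less reliable. This simulation used the unthinned share of cells with T, such as 88.28% in Epi-CE, where the thinned data had 65.45%. Simulated cells were drawn from 1 profile per library and split by their true label. Clusters, and cells that lose their T UMIs by thinning, were thus not simulated, and recovery in the real split can differ. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9, and in R 4.3.3 with edgeR 4.0.16 for TMM factors and DESeq2 1.42.0 for size factors.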

Results

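Neuromesodermal progenitors (NMPs) are cells of the caudal embryo that give rise to spinal cord and paraxial mesoderm, and several culture protocols make cells like them from mouse pluripotent cells. Single-cell transcriptomes were collected with the 10x Chromium system from 4 such populations, with 1 library per group and 8700 cells loaded for each. ES-NMP cells came from embryonic stem cells (ESCs) that spent 2 days in N2B27 medium alone and 24 h with the GSK3 inhibitor CHIR99021, which activates WNT signalling, at 3 µM. Epi-CE, a caudal epiblast-like population, came from epiblast stem cells (EpiSCs) kept in FGF2 and activin A. Activin was then removed, FGF2 was raised to 20 ng/ml, and CHIR99021 at 3 µM was added on day 3. Epi-CE-T came from a Brachyury (T) to GFP reporter line taken through the same protocol and sorted for GFP after 72 h. Epi-NMP was made by replating Epi-CE cells for 2 further days in FGF2 and CHIR99021. All libraries were labelled with the ESC line E14Tg2a.

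The deposited table held counts of unique molecular identifiers (UMIs) for 27998 genes in 10579 cells. ES-NMP had 3288 cells and 72982631 UMIs, Epi-CE 2466 cells and 59704994 UMIs, Epi-CE-T 2201 cells and 46054056 UMIs, and Epi-NMP 2624 cells and 29927826 UMIs. The median cell held 21583, 22436 and 18965 UMIs in the first 3 of these libraries and 6426 in Epi-NMP. A column of the deposited cell table marked 57.7% of Epi-NMP barcodes FALSE (median 4720 UMIs) and 42.3% TRUE (median 19252 UMIs), against 3.24% to 5.23% marked FALSE in the other libraries. All barcodes were kept, and a value from TRUE barcodes alone is given beside any named gene whose ratio it moved by over 1.5 times. Levels are summed UMIs per 1000000 (CPM), and all 95% intervals cover counting error only. Genes called furthest up or down are those ranked among genes with at least 200 UMIs over both libraries and 50 CPM in the higher one, so a gene at a lower level can have a larger ratio. With 1 library per group no difference has a replicate check, and library and condition could not be told apart.

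The loci of the 4 genes followed throughout are T on chromosome 17 (8434423 to 8442496, plus strand), Sox2 on chromosome 3 (34650405 to 34652461, plus strand), Nkx1-2 on chromosome 7 (132594878 to 132599637, minus strand) and Cdx2 on chromosome 5 (147300805 to 147307270, minus strand), all protein-coding, in build mm10. T encodes the Brachyury transcription factor of primitive streak and notochord, Sox2 a factor of pluripotent and neural cells, Nkx1-2 a homeobox factor of the caudal epiblast, and Cdx2 a caudal homeobox factor. T was at 103 CPM in ES-NMP (100.7 to 105.4), 429.7 in Epi-CE (424.4 to 435), 380.1 in Epi-CE-T (374.5 to 385.7) and 226.1 in Epi-NMP (220.8 to 231.6). Sox2 was at 71.7, 31.2, 48.3 and 88.5 CPM in the same order of libraries. Nkx1-2 was at 134.1, 180.7, 12.6 and 74.6 CPM, and Cdx2 at 243.6, 120.9, 4.67 and 316.4 CPM.

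**Figure D1:**
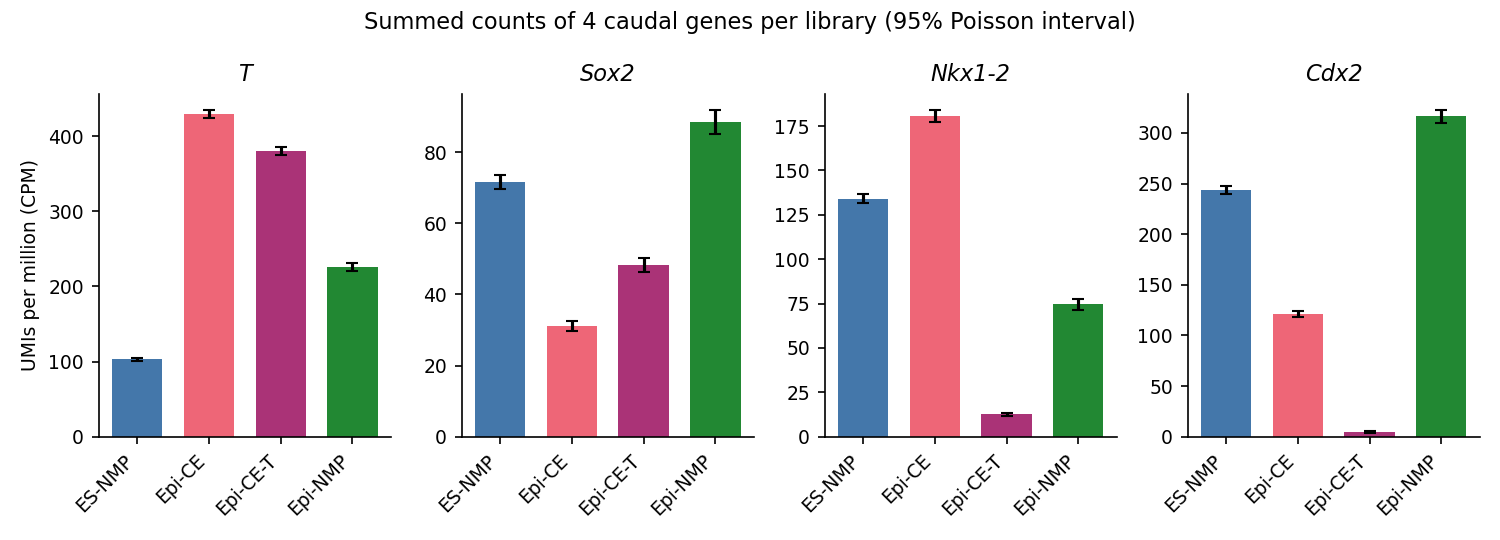
Levels of T, Sox2, Nkx1-2 and Cdx2 in CPM, 1 panel per gene with its own linear axis and 1 bar from 0 per library, with exact 95% Poisson intervals that cover counting error only. The Epi-CE-T bars for Nkx1-2 (12.6 CPM) and Cdx2 (4.67 CPM) lie far below those of the other 3 libraries.

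Epi-CE against ES-NMP set the EpiSC-derived population beside the ESC-derived one. T was 4.17-fold higher in Epi-CE (4.06 to 4.28) and Nkx1-2 was 1.35-fold higher (1.31 to 1.39), while Sox2 was 2.30-fold lower (2.18 to 2.42) and Cdx2 was 2.02-fold lower (1.96 to 2.07). After thinning to 4000 UMIs, Sox2 was detected in 51.6% of the naive pluripotent-like cells of ES-NMP but in 13.5% of its caudal epiblast or NMP-like cells, against 12.0% of Epi-CE cells. Naive pluripotency genes and Hox genes were far lower in Epi-CE, neural genes were lower, and node and notochord genes, glycolysis genes and immediate early genes were higher. Among the caudal epiblast and NMP genes, 10 of 20 measured members were at least 1.5-fold lower and 3 were higher. The median log2 ratio of this list was -0.52 (-0.61 to -0.44), at the 0.01 percentile of 10000 random lists of the same size matched on expression, which is a description of these libraries. Hes3, a transcriptional repressor, was 69.3-fold lower, the growth factor gene Fgf17 was 5.27-fold lower, and Cdx4, a relative of Cdx2, had 0 counts in Epi-CE and was at least 78.5-fold lower.

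Of 15 naive pluripotency genes 12 were lower (median log2 ratio -6.39, percentile 0), and 24.2% of ES-NMP cells fell in a cluster with naive pluripotency markers. Zfp42 was at 0.0670 against 166.9 CPM, 2491-fold lower (973 to 9144), Dppa3 was 1481-fold lower on 3 counts (507 to 7184), Nr0b1 was 751-fold lower on 1 count (135 to 29694) and Tdh, threonine dehydrogenase, was 471-fold lower. Dppa5a was 414-fold lower, with the reservation that near-identical copies exist. Core and primed pluripotency genes were mixed, with 8 of 17 lower and 2 higher (median -0.39): Dnmt3l was 74.2-fold lower and Nanog 4.00-fold lower, whereas Pou3f1 was 4.10-fold higher. Of the Nodal and Activin pathway, 6 of 9 genes were lower (median -0.97), among them Gdf3 by 18.3-fold and the Nodal inhibitors Lefty2 by 9.16-fold and Lefty1 by 2.51-fold.

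Hox genes, which mark position along the body axis, were lower in Epi-CE in 10 of 11 members of paralogue groups 1 to 4 (median -1.50) and in 13 of 14 of groups 5 to 9 (median -5.21). Hoxb6 was 232-fold lower (99.1 to 715), Hoxc8 175-fold, Hoxb9 97.0-fold and Hoxb4 5.25-fold lower, and the only measured member of groups 10 to 13, Hoxa10, was 91.6-fold lower on 1 count (16.1 to 3651). Of 15 neural genes 12 were lower (median -1.47): Sox1 was 15.6-fold, Hes5 14.6-fold and Pax3 13.02-fold lower. Crabp1, a retinoic acid binding protein gene, was 15.0-fold lower, Trh, the thyrotropin-releasing hormone gene, 55.5-fold lower and Mylpf, a myosin light chain gene, 34.4-fold lower. The neural-like cluster 15, with 6.54% of ES-NMP cells, had Sox1 13.8-fold, Hes5 18.8-fold and Crabp1 55.7-fold above all other cells clustered. The library ratios of these genes therefore need not hold for most ES-NMP cells. Hprt, the purine salvage enzyme gene, was 253-fold lower (190 to 343).

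All 9 node and notochord genes were higher in Epi-CE (median 3.81, percentile 100): the secreted signal Shh was at 4.37 CPM against 3 counts in ES-NMP, 106-fold higher (36.0 to 519), Foxa2 was 28.0-fold, Foxj1 18.5-fold and Chrd 15.1-fold higher. Of 15 glycolysis genes 13 were higher (median 1.18), including Pgk1 by 3.51-fold, Aldoa by 2.80-fold and the glucose transporter gene Slc2a1 by 2.61-fold. Of 13 dissociation stress and immediate early genes 8 were higher (median 1.29), with Junb at 4.83-fold, Fos at 4.50-fold and Jun at 4.42-fold. Among the genes furthest up by rank were Gbp2 (25.4-fold) and Gbp2b (22.7-fold), interferon-inducible GTPases similar enough to share reads, followed by Clu (22.1-fold, 214.2 against 9.67 CPM), Sprr2a3 (17.7-fold, a member of a family of close copies), the apelin receptor gene Aplnr (14.1-fold), Anxa2 (13.5-fold), Tmem176a (13.2-fold), Tmem176b (8.91-fold) and Rgs17 (8.74-fold). Vim, vimentin, was 5.31-fold higher in a list of epithelial and mesenchymal genes with a median of 0.37. Medians lay close to 0 for the WNT targets (0.04), the primitive streak genes (-0.00), the Notch pathway (-0.12) and the G2 and M phase genes (-0.07), and 6 of 20 S phase genes were lower (median -0.36). Hoxaas3, an antisense gene that was 31.8-fold lower, stays uncertain because the strand setting of the counting was not given in the sources used here. Without the naive pluripotent-like cells the NMP list median was -0.75.

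Epi-NMP against ES-NMP compared the populations that both protocols call NMPs. T was 2.20-fold higher in Epi-NMP (2.12 to 2.27), Sox2 was 1.23-fold higher (1.18 to 1.29), Cdx2 was 1.299-fold higher (1.27 to 1.33) and Nkx1-2 was 1.80-fold lower (1.72 to 1.88). Pluripotency genes and Nodal pathway genes were lower in Epi-NMP, and posterior Hox genes, paraxial mesoderm genes, Notch pathway genes and node and notochord genes were higher. The caudal epiblast and NMP list went both ways, with 6 of 20 members higher, 8 lower and a median log2 ratio of -0.24 (-0.29 to -0.15, percentile 2.05). Epha5, an ephrin receptor gene, was 7.88-fold higher, whereas Wnt8a was 18.6-fold and Hes3 13.5-fold lower. Cdx4 was 59.1-fold lower on 2 counts (16.2 to 489.9), and 88.4-fold lower over TRUE barcodes.

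Of 15 naive pluripotency genes 13 were lower (median -5.62). Zfp42 was 4995-fold lower on 1 count (896 to 197293) and at least 1240-fold lower over TRUE barcodes, Dppa5a was 3758-fold lower (1907 to 8705, copies as above), Tdh 1533-fold lower, and Dppa3, with 0 counts in Epi-NMP, at least 742-fold lower. Of 17 core and primed pluripotency genes 12 were lower and 0 higher (median -2.28). The Nodal co-receptor gene Tdgf1 was 1821-fold lower on 1 count (327 to 71946; at least 448-fold over TRUE barcodes), Nanog was 218-fold lower (110.3 to 504), and Utf1 was 124-fold lower over all barcodes and 191-fold over TRUE ones. The naive pluripotent-like cluster 4 of ES-NMP had Utf1 11.1-fold, Tdgf1 9.39-fold and Nanog 9.19-fold above all other cells clustered. In the Nodal and Activin list 8 of 9 genes were lower (median -5.31), with Lefty1 at 143-fold and Lefty2 at 158-fold. Trh was 206-fold lower (321-fold over TRUE barcodes), and Hprt was 217-fold lower (150.1 to 327). Of 7 measured trophoblast genes 5 were lower (median -1.15), and of 5 fibroblast genes 4 were lower (median -1.71).

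In Hox paralogue groups 1 to 4, 8 of 11 genes were higher in Epi-NMP (median 1.40) and Hoxb1 was 3.58-fold lower. In groups 5 to 9, 13 of 14 were higher (median 1.56), with Hoxc9 at 9.52-fold, Hoxa9 at 5.13-fold and Hoxa7 at 4.97-fold. All 5 measured genes of groups 10 to 13 were higher (median 3.47), including Hoxc10 by 37.5-fold, Hoxd10 by 28.0-fold and Hoxa10 by 6.08-fold. Of 17 paraxial and presomitic mesoderm genes 13 were higher (median 1.46, percentile 100): Meox1, a somite homeobox gene, was 30.0-fold, Foxc2 15.2-fold and Mesp2 8.15-fold higher. Of 10 Notch pathway genes 8 were higher (median 1.24), with Hey1 at 3.27-fold, Hes7 at 2.74-fold and Hes1 at 2.72-fold. In the retinoic acid list 4 of 7 were higher (median 0.63), led by Dhrs3 at 15.7-fold and Cyp26a1, which degrades retinoic acid, at 6.19-fold. Node and notochord genes were higher in 6 of 8 members (median 3.61), Shh by 142-fold on 3 counts in ES-NMP (47.9 to 697) and Chrd by 20.2-fold. Neural genes had no shared direction: 7 of 16 were higher and 5 lower, and their median of 0.23 became -0.05 when every cell weighed the same. Ncam1, a neural adhesion molecule gene, was 9.70-fold and Neurog2 11.2-fold higher. Sox1, a marker of the neural-like cluster 15 of ES-NMP, was 10.2-fold lower.

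Among the remaining genes furthest up were Arg1, arginase (22.5-fold), Igfbp5 (19.7-fold), the selenoprotein gene Sepp1 (14.6-fold), Lmo2 (12.7-fold) and Ppp1r1a (9.81-fold). Notch2 was 10.3-fold higher over all barcodes and 3.65-fold over TRUE ones. The antisense gene Hoxb5os was 10.6-fold higher, under the same reservation on strand as Hoxaas3. The FGF feedback list (median 0.46) had 4 of 12 members higher, and its member Spry2 was 4.31-fold higher but 1.68-fold over TRUE barcodes. Stress and immediate early genes had 6 of 13 higher and 2 lower (median 0.52, percentile 99.95), with Jun at 3.65-fold, Junb at 3.52-fold and Fos at 3.15-fold. BMP targets had 6 of 11 higher (median 0.86), with Id4 at 3.10-fold and Id2 at 2.59-fold. The epithelial genes Esrp1, Cdh1 and Cldn7 were 42.6-fold, 31.2-fold and 17.8-fold lower, in a list with 6 of 12 members higher and 5 lower. Glycolysis genes had a median of 0.04, which became -0.04 when every cell weighed the same. Without the naive pluripotent-like cells of ES-NMP the NMP list median was -0.53.

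Epi-NMP against Epi-CE compared the replated cells after the extra days with the population they came from. Sox2 was 2.84-fold higher in Epi-NMP (2.67 to 3.01) and Cdx2 2.62-fold higher (2.54 to 2.70), while Nkx1-2 was 2.42-fold lower (2.32 to 2.54) and T was 1.90-fold lower (1.85 to 1.95). Hox genes of every measured paralogue range, neural genes and paraxial mesoderm genes were higher, and pluripotency, Nodal pathway and glycolysis genes were lower. In the caudal epiblast and NMP list 9 of 19 genes were higher and 6 lower, with a median log2 ratio of -0.26 (-0.36 to -0.09, percentile 3.73). Epha5 was 23.8-fold, Hes3 5.15-fold and Wnt5a 4.52-fold higher, and Wnt8a was 19.7-fold lower.

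All 14 measured genes of Hox groups 5 to 9 were higher (median 6.02, percentile 100), as were all 4 of groups 10 to 13 (median 7.60) and 9 of 11 of groups 1 to 4 (median 2.93). Hoxc9 was at 69.9 against 0.0838 CPM, 835-fold higher (357 to 2573). Hoxc8 was 451-fold, Hoxb9 263-fold, Hoxb8 79.5-fold, Hoxa7 26.4-fold and Hoxb4 18.8-fold higher, and Hoxc10, on 1 count in Epi-CE, was 1197-fold higher (214 to 47356). The antisense genes Hoxb5os (1056-fold) and Hoxaas3 (139-fold) were also among the 10 highest. Of 13 neural genes 9 were higher (median 3.31, percentile 100): Neurog2, a proneural factor gene, was 70.8-fold, Pax3 27.1-fold, Zic1 16.6-fold and Ncam1 9.91-fold higher. Of 17 paraxial and presomitic mesoderm genes 12 were higher (median 1.55), including Meox1 by 48.2-fold, Foxc2 by 37.3-fold and Mesp2 by 20.9-fold. Notch pathway genes were higher in 7 of 10 members (median 1.18), with Hes5 at 14.2-fold and Hes7, a segmentation clock gene, at 6.97-fold. Retinoic acid genes were higher in 4 of 7 (median 1.13), with Dhrs3 at 11-fold. Igfbp5 was 10.1-fold higher.

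Core and primed pluripotency genes were lower in 11 of 16 members (median -2.07). Pou5f1, which encodes OCT4, was at 9.99 against 427.3 CPM, 42.8-fold lower (38.2 to 48.1), Nanog was 54.4-fold lower, Utf1 was 46.3-fold lower (70.8-fold over TRUE barcodes) and Tdgf1 was 1030-fold lower on 1 count (185 to 40706; at least 256-fold over TRUE barcodes). Of 7 measured naive pluripotency genes 6 were lower (median -1.97). Lefty1 was 57.2-fold and Nodal 6.41-fold lower in a Nodal and Activin list with 6 of 9 members lower (median -4.11). Glycolysis genes were lower in 12 of 15 (median -1.06), with Pfkp at 11.3-fold and Slc2a3 at 3.45-fold, and Aldoc, an aldolase gene outside that list, was 20.1-fold lower. Of 12 epithelial and mesenchymal genes 6 were lower (median -0.99): Cdh1, E-cadherin, was 20.3-fold, Epcam 17.7-fold and Cldn7 17.1-fold lower. The keratin genes Krt19 (14.9-fold) and Krt8 (10.5-fold, with pseudogene copies) were also lower. Fst, the activin antagonist follistatin, was 35.0-fold, Alox15 33.4-fold, F2rl1 29.3-fold and Pim2 18.0-fold lower. Of 13 stress and immediate early genes 5 were lower (median -0.50), and of 9 p53 and apoptosis genes 4 were lower (median -0.48), among them Trib3 by 6.29-fold. S phase (median 0.08), G2 and M phase (-0.01) and WNT target (0.16) medians lay near 0, and Spry2, 5.35-fold higher over all barcodes, was 2.00-fold higher over TRUE ones.

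The library labelled Epi-CE-T was sorted for a T reporter, so T was read first. T was not higher there than in unsorted Epi-CE: it was at 380.1 against 429.7 CPM, 1.13-fold lower (1.11 to 1.15). The sort was on GFP, and no GFP sequence was analysed here. Without thinning, T was already found in 88.3% of unsorted Epi-CE cells. The T RNA level therefore cannot tell whether the sort worked. Sox2 was 1.55-fold higher (1.45 to 1.65), while Cdx2 was 25.9-fold lower (22.6 to 29.8) and Nkx1-2 was 14.4-fold lower (13.2 to 15.7). Caudal epiblast, primitive streak, paraxial mesoderm and pluripotency genes were lower in the library labelled Epi-CE-T, and Shh and neural genes were higher. Of 18 measured caudal epiblast and NMP genes 13 were lower and 1 was higher, with a median log2 ratio of -1.85 (-1.95 to -1.81, percentile 0). Cdx1 was 33.9-fold, Wnt3a 32.1-fold and Evx1 16.5-fold lower. The reporter line and the sort both differed from Epi-CE, so neither can be separated from the other.

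Primitive streak genes were lower in 7 of 11 members (median -2.02), with Mixl1 at 29.4-fold and Lhx1 at 4.28-fold. Paraxial and presomitic mesoderm genes were lower in 10 of 14 and higher in 0 (median -1.58), with Aldh1a2 at 15.0-fold, Tbx6, a presomitic mesoderm factor gene, at 10.4-fold and Hes7 at 8.27-fold. Core and primed pluripotency genes were lower in 12 of 16 (median -1.45), including Tdgf1 by 13.3-fold. Fgf4 was 170-fold lower on 1 count (30.1 to 6733; at least 55.7-fold over TRUE barcodes). Naive pluripotency genes were lower in 5 of 7 (median -1.84). Fgf8, a caudal growth factor gene, was 20.6-fold lower (4.63 against 95.3 CPM), and Gbx2 (13.7-fold), Wnt6 (12.3-fold), Fst (14.6-fold), the meiotic gene Sycp3 (21.3-fold), Alox15 (9.41-fold), Igfbp3 (9.16-fold) and Sprr2a3 (14.7-fold, copies as above) were others furthest down among the genes ranked. WNT targets were lower in 8 of 14 (median -0.76). Hox groups 1 to 4 were lower in 5 of 9 (median -1.48), with Hoxb1 at 15.3-fold, and groups 5 to 9 had a median of -0.37 over 6 measured genes.

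Hprt stood highest among the genes ranked, at 137.7 against 0.804 CPM, 171-fold higher (129 to 233). Pomc, the pro-opiomelanocortin gene, was at 1380 against 17.8 CPM, 77.5-fold higher (72.9 to 82.4), followed by the cartilage and notochord collagen gene Col2a1 (52.9-fold), vitronectin, Vtn (35.2-fold), Lmx1a (25.3-fold), Samd3 (21.5-fold), Shh (18.1-fold, 79.0 against 4.37 CPM), Igfbp5 (14.1-fold), Alcam (12.8-fold) and Mfap4 (9.57-fold). Node and notochord genes had a median of 0.08, with 4 of 9 higher and 1 lower: besides Shh, Sox9 was 6.52-fold and Chrd 5.75-fold higher, and Noto was 2.83-fold lower. Of 13 neural genes 9 were higher (median 1.84, percentile 100), with Pax3 at 19.6-fold, Nkx6-1 at 13.3-fold and Sox1 at 7.43-fold. Definitive endoderm genes were higher in 5 of 11 and lower in 3 (median 0.55), with Foxa1 at 7.27-fold and Cer1 at 5.51-fold, and fibroblast genes in 4 of 6 (median 1.83), with Dcn, decorin, at 31.8-fold. S phase genes were lower in 6 of 20 (median -0.39), whereas G2 and M phase genes had a median of 0.20, with Aurkb at 1.74-fold and Hmmr at 1.69-fold higher. The epithelial genes Cldn7 and Cdh1 were 8.85-fold and 7.70-fold lower, in a list with 6 of 12 lower (median -0.81).

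Some lists moved less or were measured in few members. Lateral plate and extraembryonic mesoderm genes had medians of 0.87, 0.66, -0.21 and -0.87 in the order in which the comparisons are given above. In the same order the extraembryonic endoderm medians were -0.04, 0.25, -0.05 and 0.60, the neural crest medians 0.60, 1.06, 0.79 and 1.39 over at most 5 genes, and the blood and endothelium medians 0.59, 1.29, 0.70 and -0.97 over 3 genes. None of the 7 genes of the 2-cell-like list reached the minimum of 50 UMIs over both libraries of a comparison.

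**Figure D2:**
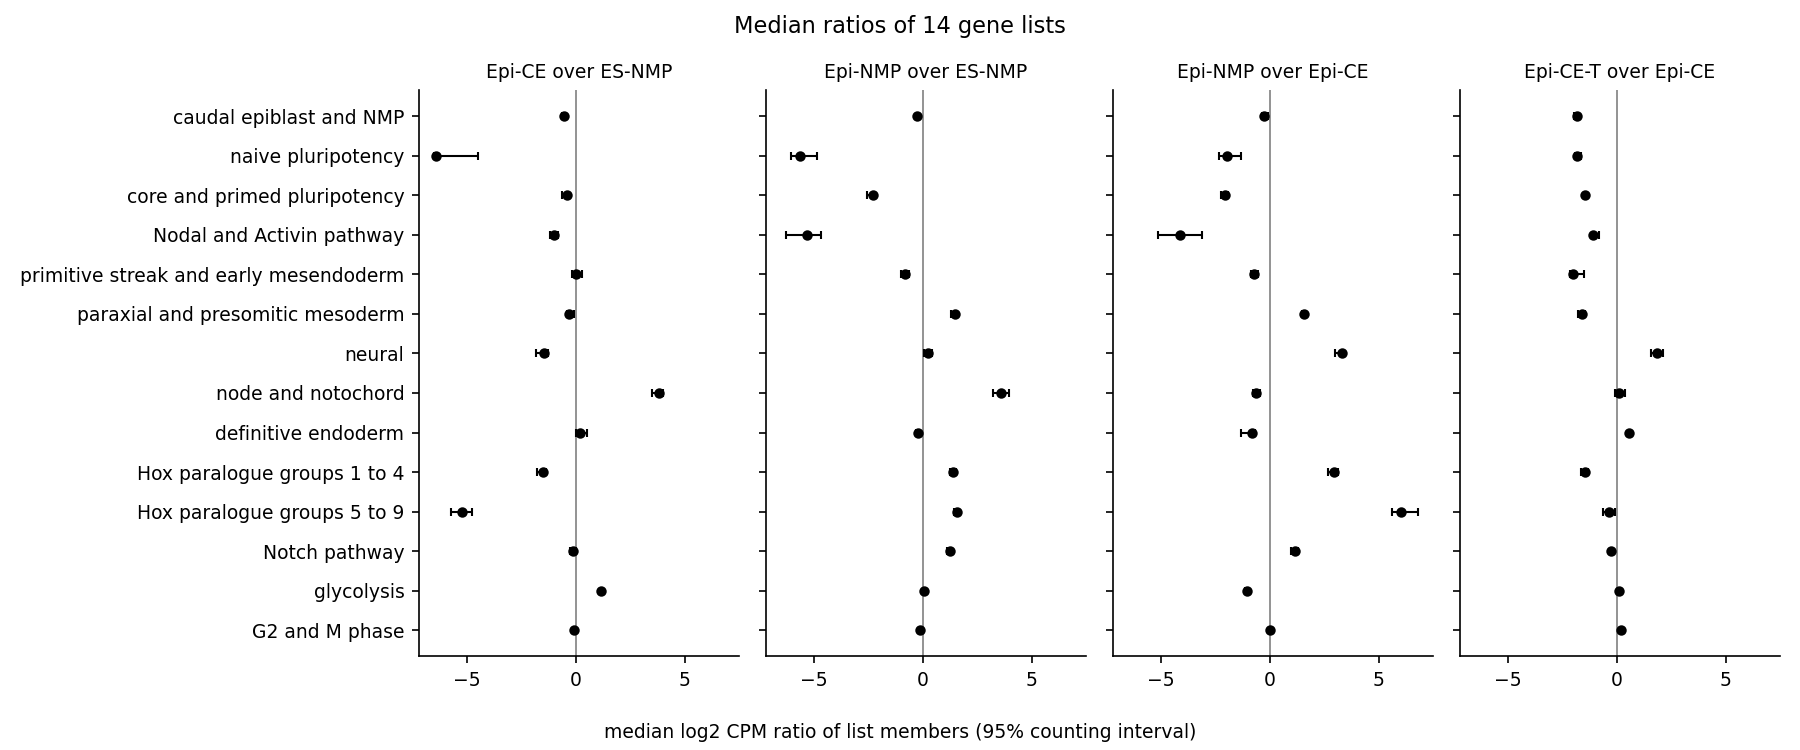
Median log2 CPM ratio of 14 of the fixed gene lists in the 4 comparisons, 1 point per list and comparison, with 95% intervals from Poisson resampling of the counts. Hox groups 5 to 9 lie at -5.21 in Epi-CE over ES-NMP and at 6.02 in Epi-NMP over Epi-CE, and the caudal epiblast and NMP list at -1.85 in Epi-CE-T over Epi-CE.

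Co-detection of T and Sox2 in the same cell, the usual mark of an NMP, was compared after thinning each cell to 4000 UMIs, which left out 204 Epi-NMP cells and none elsewhere. Both genes were detected in 2.46% of ES-NMP cells (exact interval 1.96 to 3.05), 7.83% of Epi-CE cells (6.80 to 8.96), 7.04% of Epi-CE-T cells (6.01 to 8.19) and 9.21% of Epi-NMP cells (8.09 to 10.4). The products of the single-gene shares, which unrelated detection would give, were 4.90%, 7.86%, 9.29% and 9.18%. The interval of co-detection lay below that product in ES-NMP and in the library labelled Epi-CE-T, and held it in Epi-CE and Epi-NMP. That product takes a library as 1 population: in ES-NMP, the naive pluripotent-like cluster 4 had T in 7.55%, Sox2 in 51.6% and both in 3.14% of cells, and the caudal epiblast or NMP-like cluster 3 had T in 40.3%, Sox2 in 13.5% and both in 3.73%. In Epi-CE-T, T and Sox2 were likewise split between cluster 11 (T 11.9%, Sox2 25.4%, both 2.06%) and the notochord-like cluster 6 (T 89.98%, Sox2 7.20%, both 6.89%), so a share below the product does not show that the genes avoid each other within a cell type. Products within clusters were not computed, so whether mixing of clusters accounts for the whole shortfall was not tested. T alone was detected in 23.2%, 65.5%, 63.7% and 40.7% of cells and Sox2 in 21.1%, 12.0%, 14.6% and 22.6%, in the same order as their CPM. As a possible background, T was detected in 1.86% of ES-NMP cells in the neural-like cluster 15 (median 20676 UMIs against 21583 in the library) and Sox2 in 1.59% of those in the paraxial mesoderm-like cluster 17 (median 21244 UMIs). Whether these cells express the genes was not tested. Background could not be read in the other libraries, where the lowest shares in clusters of at least 50 cells were 52.0% with T and 3.21% with Sox2 in Epi-CE, 11.9% and 7.20% in Epi-CE-T, and 25.7% and 6.64% in Epi-NMP. Without thinning both genes were found in 18.6%, 30.6%, 29.5% and 22.1% of cells, against products of 24.1%, 31.8%, 33.3% and 20.1%, so that Epi-NMP (20.6 to 23.8) then lay above its product. Depth was uneven in Epi-NMP, with medians of 4720 UMIs in FALSE and 19252 in TRUE barcodes. Uneven depth alone can raise co-detection above the product, so this excess does not show that T and Sox2 go together. With at least 2 UMIs of each gene after thinning the shares were 0.0608%, 0.730%, 0.818% and 0.950%. Over TRUE barcodes the Epi-NMP share was 11.3% against a product of 12.0%. After thinning, the unnamed cluster 7 had T in 41.9%, Sox2 in 45.1% and both in 18.4% of its 599 Epi-NMP cells. That was the highest share with both among clusters with at least 50 cells of a library.

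**Figure D3:**
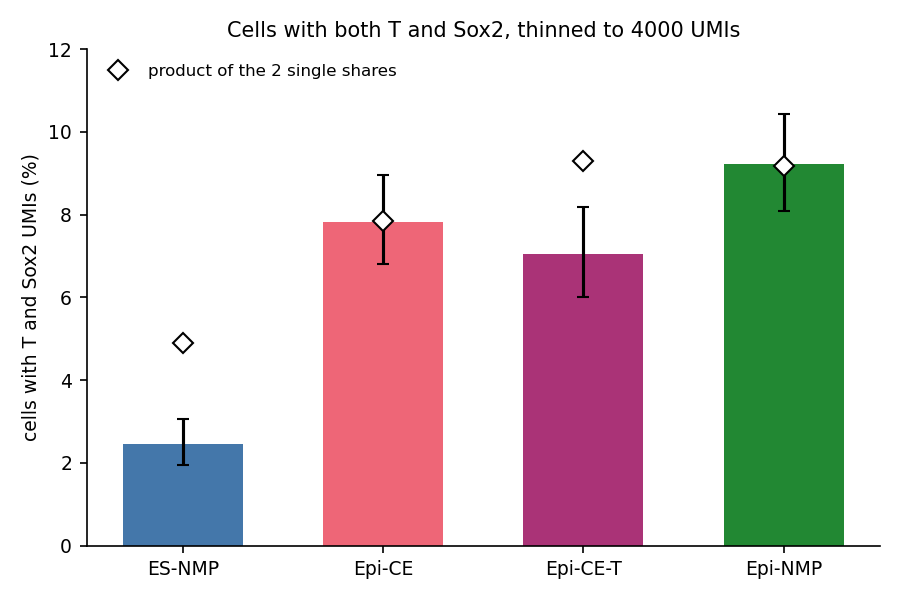
Percent of cells with a UMI of both T and Sox2 after thinning to 4000 UMIs, 1 bar from 0 per library with exact 95% intervals that cover counting error only, and a diamond at the product of the single-gene shares. The ES-NMP bar ends at 2.46% against a product of 4.90%, and the Epi-NMP bar at 9.21% against 9.18%.

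Clustering of the 4 libraries together gave 20 clusters, and with 1 library per group a cluster mostly of 1 library may be that library and not a cell type. In ES-NMP 27.7% of cells were caudal epiblast or NMP-like (cluster 3), 24.2% naive pluripotent-like (cluster 4), 6.54% neural-like (cluster 15) and 3.86% paraxial mesoderm-like (mainly cluster 17), and 37.4% were in unnamed clusters. In Epi-CE 9.21% were paraxial mesoderm-like (mainly cluster 14) and 89.3% unnamed. The library labelled Epi-CE-T, whose sort and line can set these shares, had 29.0% notochord-like (cluster 6), 24.6% definitive endoderm-like (cluster 8) and 45.8% unnamed cells. Besides its 5 endoderm markers, cluster 8 had markers of other classes. Among them were Chrd (5.24-fold above the other cells), Shh (3.65-fold) and Nog (3.44-fold) of notochord, and Dcn, Col1a1 and Col1a2 of fibroblast. In Epi-NMP 30.8% were paraxial mesoderm-like and 68.8% unnamed, and most of the former lay in cluster 10, whose 537 cells were 91.8% FALSE-marked with a median of 4872 UMIs, the rest mainly in cluster 13. The neural-like share of ES-NMP and the paraxial mesoderm-like shares of ES-NMP and Epi-CE stayed within their intervals under every setting tried. The other named shares did not: the notochord-like share ranged from 0 to 59.3%, the endoderm-like share from 0 to 24.6%, the caudal or NMP-like share from 11.6% to 60.2%, the naive-like share from 10.9% to 25.0% and the Epi-NMP paraxial share from 8.69% to 35.8%. With each library clustered by itself, 14.8% of Epi-CE and 15.5% of Epi-NMP cells were also caudal epiblast or NMP-like, beside 11.6% of ES-NMP, although the joint clustering put 0% and 0.191% of them in that class. Other classes changed as well, such as Epi-NMP neural-like (10.1% against 0.0762% jointly) and notochord-like cells (6.48% against 0%). Markers were scored against the other cells of the same clustering, so these shares are unlike measures. A joint share of 0% does not show that such cells were absent. Clusters with at least 3 markers of a class that stayed unnamed under rules partly set after the first clustering were cluster 1 (3 markers each of primed epiblast and of caudal epiblast or NMP, 31.6% of ES-NMP cells), cluster 2 (3 each of neural and paraxial mesoderm, 38.6% of Epi-NMP), cluster 7 (neural, 22.8% of Epi-NMP), cluster 9 (4 each of notochord and definitive endoderm, 24.0% of Epi-CE-T and 0.649% of Epi-CE), cluster 12 (fibroblast, 2.95%, 4.99%, 1.05% and 1.03% of the libraries in the order above) and cluster 16 (notochord, 3.00% of Epi-CE and 4.88% of Epi-NMP). Each of these clusters held under 0.3% of every library not named beside it. Cluster 7 also had 3 markers of caudal epiblast or NMP beside its 4 neural ones. In cluster 2, 93.8% of cells were FALSE-marked (median 4764 UMIs), against 2.28% in cluster 7 (median 20258 UMIs), and cluster sizes were not compared between libraries.

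**Figure D4:**
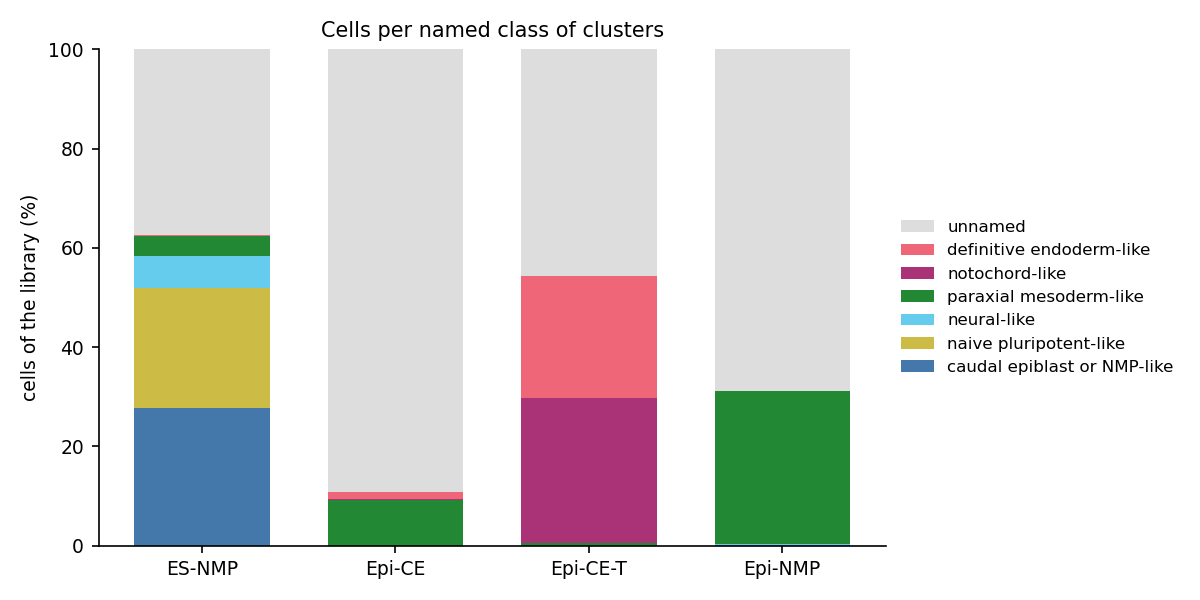
Percent of cells of each library in each named class or in unnamed clusters, as stacked bars from 0 without intervals, 1 bar per library. Unnamed clusters hold 37.4% of ES-NMP cells and 89.3% of Epi-CE cells.

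Genes that went with T inside each library were read from thinned counts summed over cells with and without a T UMI. In ES-NMP cells with T, Fgf8 was higher by 2.38 on the log2 scale, Mixl1 by 2.14 and Rspo3 by 2.06, while Dnmt3l (-3.28), Acta2 (-3.22), Crabp1 (-2.69) and Zfp42 (-2.43) were lower. There 13 of 16 caudal epiblast and NMP genes were at least 1.5-fold higher (median 0.98), and 11 of 13 naive pluripotency genes were lower (median -1.69). In Epi-CE cells with T, 7 of 15 caudal epiblast and NMP genes were higher (median 0.44), as were all 6 measured node and notochord genes (median 1.70). Single genes in Epi-CE with the highest ratios were Psmb8 (1.94) and Lefty1 (1.82), and Pim2 (-1.50) and Fn1 (-1.11) had the lowest. In the library labelled Epi-CE-T, cells with T had higher Cd36 (2.27), Shh (2.13) and Col2a1 (2.06) and lower Crabp1 (-4.18), Fgfbp3 (-3.06) and Pou5f1 (-2.39), and 13 of 20 S phase genes were lower (median -0.72). In Epi-NMP, cells with T had higher Alcam (2.55), Krt19 (2.48) and Clu (1.98), all 5 measured node and notochord genes were higher (median 2.58), and 8 of 13 paraxial mesoderm genes were lower (median -0.77), among them Meox1 (-1.33) and Tcf15 (-1.06).

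Across genes, which are not independent replicates, these ratios were set against the ratio of Epi-CE-T over Epi-CE computed from other cells. Pearson's r was 0.599 for cells of the library labelled Epi-CE-T (rho 0.565, 2822 genes), 0.189 for Epi-NMP (rho 0.269, 4589 genes), 0.018 for Epi-CE (rho 0.151, 3068 genes) and -0.087 for ES-NMP (rho 0.0435, 5454 genes). From unthinned counts the Epi-CE value was -0.167, so it had no stable sign. Epi-CE-T is the numerator and Epi-CE the denominator of the library ratio, and a random part of their cells gave each ratio. Genes high in cells with T can thus raise r for Epi-CE-T and lower it for Epi-CE, even with no cell shared. The values of Epi-CE-T and Epi-CE are therefore not like measures to those of ES-NMP and Epi-NMP. Of the 10 genes with the highest ratios per library, 2 to 6 were also among the 10 highest from unthinned counts, and of the 10 lowest only 1 or 2. With TRUE barcodes alone, 5 of the 10 highest and 3 of the 10 lowest were shared in Epi-NMP, and 9 or 10 elsewhere, so single genes named for cells with T depend on the processing.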

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

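Of the tests below, those on free RNA and on low-UMI barcodes of the other libraries were chosen after the result had been seen, and the test on GC content and length before it. The deposited TRUE or FALSE mark was not part of any comparison, and it drew attention because it marked 57.66% of Epi-NMP barcodes FALSE (1513 of 2624) against 3.24% to 5.23% in the other libraries. FALSE barcodes of Epi-NMP had a median of 4720 UMIs and 4.24% mitochondrial UMIs, TRUE ones 19252 and 2.59%. In all libraries, 80 FALSE barcodes passed both minimums that every TRUE barcode met: 19 in ES-NMP, 29 in Epi-CE, 32 in Epi-CE-T and 0 in Epi-NMP.

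Within Epi-NMP, 29 of 7038 genes compared were at least 4-fold higher per UMI in FALSE than in TRUE barcodes and 1 was lower, led by Abhd2 (10.5-fold), Notch2 (8.48-fold), Spry2 (7.49-fold) and Slc39a1 (7.06-fold), and the set took 1.92% of UMIs against 0.359%. Actb, also in the set, was at 14586 CPM in FALSE and 2731 CPM in TRUE barcodes. It held most of the set's UMIs, so shares of UMIs of the set mainly reflect Actb. GC content or transcript length is argued against by a median log2 ratio of 2.72 for the set after correction for both, against 2.45 before. Free RNA in droplets without a cell stays open: the set's share of UMIs, mainly that of Actb, was alike in the 81 FALSE barcodes with a Meox1 UMI and the 1432 without, at a ratio of 0.9949 (0.9725 to 1.018), as 1 mixture would give, while the somite gene Tcf15, outside the set, was 7.92-fold higher per UMI (5.93 to 10.5) in those with Meox1. A first test on Tcf15 alone was replaced after its value was seen, because it did not cover the set. A property of low-UMI barcodes in general stays open: FALSE over TRUE medians of the set were 1.28 in ES-NMP, 0.21 in Epi-CE and 0.06 in Epi-CE-T. ES-NMP goes with this reading. The values of Epi-CE and Epi-CE-T decide little, because 29 of 80 and 32 of 92 FALSE barcodes there passed both minimums, against 19 of 172 in ES-NMP. Those barcodes were not low in UMIs by that measure. No biological explanation was tested.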

How the results depend on the processing

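Chosen after the data had been seen were the settings with TRUE barcodes alone, without the top 5% of Scrublet scores, without the naive pluripotent-like cells, and the TMM, DESeq2 and per-cell mean scalings of the lists other than the NMP list. No paired analysis was possible because each group has 1 library. Medians of the NMP list kept their sign in all 4 comparisons under every setting, from -0.75 to -0.45, -0.53 to -0.22, -0.33 to -0.20 and -2.12 to -1.83 in the order of the report. The ends of these ranges that left the counting intervals were -0.75 and -0.53 without naive pluripotent-like cells, and, for Epi-CE-T over Epi-CE, -2.01 as a mean over cells and -2.12 with cells between the 10th and 90th percentile of UMIs. Shares of cells with both T and Sox2 fall with fewer UMIs by construction. In the order ES-NMP, Epi-CE, Epi-CE-T and Epi-NMP they were 18.55%, 30.62%, 29.53% and 22.14% unthinned, 1.004%, 3.041%, 2.453% and 3.62% at 2000 UMIs, and 0.06083%, 0.7299%, 0.8178% and 0.9504% with at least 2 UMIs of each gene. Another seed gave 6.448% in Epi-CE, and TRUE barcodes gave 11.25% in Epi-NMP. The ES-NMP naive-like share was 21.69% with TRUE barcodes and 10.92% with each library clustered by itself. The ES-NMP caudal epiblast or NMP-like share was 60.19% at resolution 0.5, 42.61% at 2.0, 34.82% without cell cycle genes and 11.62% clustered by itself. For the same settings in the same order, with TRUE barcodes added last, the notochord-like share of Epi-CE-T was 0%, 52.34%, 0%, 0% and 59.32%, its endoderm-like share 0%, 0.1363%, 0.4089%, 10.5% and 19.68%, and the paraxial mesoderm-like share of Epi-NMP 8.689%, 10.52%, 35.82%, 23.32% and 34.65%. Correlations across genes with Epi-CE-T over Epi-CE were -0.139, -0.167, 0.530 and 0.152 from unthinned counts, which reversed the sign for Epi-CE, and 0.206 for Epi-NMP with TRUE barcodes. Under the mean of per-cell CPM the neural (-0.05) and glycolysis (-0.04) medians of Epi-NMP over ES-NMP reversed. Except for the depth dependence of co-detection, the cause was not tested. In all, 43 values of the main results moved, 1 reversed and 70 did not. Of the named genes' values 33 moved and 287 did not, none with a change of direction, and of the other lists' values 64 moved, 2 reversed and 390 did not. Depth limits Epi-NMP most, where 3 counts are 0.100 CPM.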

Other observations

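Of the tests below, those on dilution by cells without T, on genes that go with T within Epi-CE, on cell state and on a different cell stock were chosen after the result had been seen, and those on the T-high part of Epi-CE and on a mixture in ES-NMP before it. Imprinted genes, which are expressed from one parental allele, had list medians near 0 in every comparison (0.26, -0.26, -0.19 and 0.10) with single members far from it. H19 was 439-fold higher in the library labelled Epi-CE-T than in Epi-CE (121 to 3631, on 2 counts in Epi-CE), Plagl1 108-fold (49.2 to 295) and Igf2 7.74-fold higher. In Epi-CE against ES-NMP, Plagl1 was 36.8-fold lower, H19 29.0-fold lower on 2 counts (7.75 to 245), Mest 7.18-fold lower and Peg3 3.80-fold higher. Epi-NMP had 6.98-fold more Igf2 and 5.40-fold more Cdkn1c than ES-NMP, and 3.01-fold less Meg3 than Epi-CE.

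A few genes outside the lists were chosen after their values had been seen, so they stand for no wider group. Isg15 was at 1.66 CPM in ES-NMP, 37.1 in Epi-CE, 17.6 in Epi-CE-T and 7.79 in Epi-NMP, Ifi27l2a at 5.32, 39.9, 5.93 and 3.34, and Irf1 at 6.76, 25.9, 26.6 and 8.12 in the same order. The immunoproteasome gene Psmb8 was at its highest in the library labelled Epi-CE-T (5.51, 30.8, 94.0 and 10.0 CPM). S100a10 was at 118.4, 890.1, 188.3 and 140.8 CPM and S100a11 at 92.3, 780.3, 121 and 177.3, and Actb, beta-actin, was at 5768 CPM in Epi-NMP against 978 to 1627 in the others, but TRUE barcodes of Epi-NMP had 2731 CPM and FALSE ones 14586.

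T was not higher, and caudal genes were lower, in the library labelled Epi-CE-T than in Epi-CE. If the sorted cells were simply the T-high part of a population like Epi-CE, Nkx1-2 should be near its level there, but the 247 Epi-CE cells with the most T per UMI (1272 CPM of T) held 10.33 times the Nkx1-2 of Epi-CE-T (9.23 to 11.6) and Pomc at 40.3 against 1380 CPM. Compared with all Epi-CE cells, Shh (22.0 against 4.37 CPM), Pomc (40.3 against 17.8) and Nkx1-2 (129.7 against 180.7) moved part of the way toward Epi-CE-T. Shh was at 79.0 CPM in Epi-CE-T. Cdx2 did not move (122.1 against 120.9 CPM). Genes that go with T within Epi-CE had no stable relation to the library difference, with r of 0.018 across genes, rho of 0.151 and -0.167 from unthinned counts. Epi-CE is also the denominator of that difference, which can lower r. The test therefore does not decide whether such genes account for the difference. Dilution by cells without T stays open for the level of T, since its test decides nothing: without cluster 11 (437 cells, 11.9% with T), T was 1.186 times its Epi-CE level (1.163 to 1.209), but that cluster was picked for its low T share, so T had to be higher in the rest, and Epi-CE was left whole, and its verdict rule was changed after the value was known. For the caudal genes, dilution is argued against. After thinning, T was detected in 63.7% of Epi-CE-T cells (61.7 to 65.7) and 65.5% of Epi-CE cells (63.5 to 67.3). Yet 13 of 18 caudal epiblast and NMP genes were lower, with a median log2 ratio of -1.85 (-1.95 to -1.81). The reporter line, the sort and the state of the culture cannot be told apart with 1 library each, so a difference between lines or cultures remains an untested hypothesis.

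Hprt was nearly absent from Epi-CE (48 counts, 1.91% of cells with a UMI) and Epi-NMP (28 counts, 1.07%) and present in ES-NMP (14816 counts, 93.6%) and in the library labelled Epi-CE-T (6341 counts, 82.5%), although all are labelled E14Tg2a, a line known as HPRT-deficient. Cell state as the cause is argued against: over clusters with at least 100 cells, the lowest share with an Hprt UMI after thinning in the libraries with Hprt, 29.4% in cluster 6, was 22.17 times the highest in the libraries without, 1.33% in cluster 13, and 6.77 times between the nearest interval bounds. That minimum was set after seeing that, with smaller clusters, the ratio was 15.6 but 1.56 between bounds, resting on 57 cells of cluster 18 and 74 of cluster 16. A mixture of lines in ES-NMP is argued against by an excess of 3.062 percentage points of cells without Hprt over the Poisson expectation (7.89 points in Epi-CE-T, where no test was set). A different cell stock for ES-NMP and Epi-CE-T may account for it but stays open: 3 genes separated these pairs of libraries at least 16-fold, led by Hprt (147-fold) and Pdzrn4 (19.2-fold), against 1 and 12 genes for the other pairings. The 12 genes were led by Hoxc8 and Hoxb6, so such counts also take in other differences and cannot decide on stock. Kdm5d, a Y-linked gene looked at after its values were seen, had 28 counts in ES-NMP and 47 in Epi-CE-T against 0 in Epi-CE and in Epi-NMP, the same split as Hprt, but at counts too low for the 16-fold rule.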
